A study of Mus musculus with 24 samples.

How the data were processed

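Poly-adenylated or total RNA selection is not given in the sources used here. Total RNA of dendritic cells grown from mouse bone marrow was taken with silica columns, 1 µg per sample went into a stranded library kit, and the libraries were sequenced as bulk RNA-seq, per the labels. The design text gives 4 mice per strain with independent cultures, and each strain (B6, C57, PWD) has 4 libraries without treatment and 4 after LPS at 10 ng/ml for 6 hours, 24 libraries in 6 groups. The deposited values are TPM, transcript abundances scaled to a fixed total, 1 table with 55401 rows, and each library sums to 1000000. The submitters' processing notes name STAR, edgeR and the genome build mm10, without versions; the gene annotation, the counting tool and the way TPM were computed are not given in the sources used here. TPM keep no record of read depth, so the depth of each library and the counting error of low values are unknown, and genes near 1 TPM are read with that limit.

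Symbols that stood on more than 1 line were summed, 110 lines in all, which left 55291 symbols. All 24 value columns were matched to a library. Genes with 1 TPM or more in at least 4 libraries were tested, 13246 symbols, of which 12977 matched a GENCODE M21 gene, whose coordinates on mm10 are used. TPM were not rescaled for the main analysis. Values were taken as log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 6 group means over the 24 libraries (18 residual degrees of freedom) and empirical Bayes with a trend and the robust option. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and calls at an adjusted p under 0.05. There were 12 comparisons: LPS with untreated cells in each strain, each pair of strains in each treatment, and the difference of LPS responses between each pair of strains. The count of genes changed the same way in all 3 strains was taken from the first of these.

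The 30 gene lists hold 606 genes, of which 597 are in the table and 546 were tested. Of these, 29 lists had 4 or more tested members. They were tested in 9 comparisons with camera at a preset correlation between genes of 0.01, adjusted over the 29 lists, and again with the correlation estimated for each list. Some genes stand in several lists, as Ciita does in those of MHC class II and conventional dendritic cell markers, so such lists are not separate evidence. Groups, comparisons, tests, lists, the alternatives to be tried and the rule for named genes were fixed before the data were examined. The rule takes, for each of the 9 comparisons, the 6 largest rises and 6 largest falls among called genes with a mean of 10 TPM or more in the higher group and, between 2 groups, no overlap of their 4 libraries (2.86% of random splits have none), leaving out unnamed models and pseudogenes. It adds 10 fixed genes in every comparison (Tnf, Il1b, Il6, Il10, Il12b, Ifnb1, Nos2, Tlr4, Cd14 and Nnt) and up to 4 called members of each list, or 2 where none was called. The text names only a part of the genes so taken, and that part was picked with the values known; Ccl7 and Ccl2, given with coordinates, are among them.

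Libraries with the same strain and number were taken as 1 mouse, from the design text. After removal of group means, the LPS and untreated libraries of the same number correlated with r of 0.0513 to 0.176 in the 12 pairs, own partner best in 9. The mean r with the other numbers was -0.0594 to -0.0156, but removal of group means largely fixes it, so it adds no support. Libraries of the same number in different strains had r of -0.119 to 0.128 in 24 pairs, own partner best in 5. A fit with the mouse as a block was run as an alternative, with a term for the replicate number instead in comparisons between strains. Between strains the labels give the number no meaning, but in all 6 groups Xist was at 41.9 to 104 TPM in numbers 3 and 4 and near 0 in 1 and 2, where Y-linked genes were expressed, so mice 1 and 2 were taken as males and 3 and 4 as females. The other alternatives were a pseudocount of 0.1 TPM, no filter and a filter of 5 TPM, median-of-ratios scaling, quantile normalization, empirical Bayes without trend and robust, a fit of only the groups compared, a minimum absolute log2 fold change of 1, the estimated correlation, and leaving out each library in turn. Alternatives chosen after seeing the data were a term for sex, only the mice numbered 1 and 2 or 3 and 4, and TPM without structural RNA.

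Structural RNA (7SL, 7SK, RNase P, RNase MRP and mitochondrial rRNA) took 28.8% to 44.2% of TPM, with PWD_Untreated and C57_LPS split by mouse number (higher in 1 and 2), mitochondrial mRNA 1.14% to 2.18% and pseudogenes 1.19% to 4.15%; 10731 to 12663 genes stood at 1 TPM or more. Median-of-ratios factors ran from 0.703 to 1.36. No pair of libraries held identical values. The fit was tested on simulated data with 200 changed genes per comparison over 13246 genes: 13.4% to 62.7% were recovered at a true log2 change of 0.5, 77.6% to 98.5% at 1 and 97.0% to 100% at 2, with 4 to 16 unchanged genes called. The simulated noise was independent between genes, and the real comparisons called 1510 to 9480 genes, so these rates may not carry over to the real data. Sequence copies and the parent genes of pseudogenes were found with BLAST 2.17.0 on GENCODE M21 transcripts, and figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Raw reads, genotypes and survival of mice were not analysed here.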

Results

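Mice derived from the wild carry alleles that classical laboratory strains lack, and the series asks how such natural variation bears on the response to endotoxin, the lipopolysaccharide (LPS) of Gram-negative bacteria. Dendritic cells were grown from bone marrow with the growth factor GM-CSF and either left untreated or given LPS at 10 ng/ml for 6 hours. The labels name 3 strains, B6, C57 and PWD. PWD is an inbred strain derived from wild Mus musculus musculus, and how C57 differs from B6 is not given in the sources used here. Each strain and treatment has 4 libraries, 24 in all, and the values are TPM (transcript abundance scaled to a fixed total per library). A difference is called when limma gives a Benjamini-Hochberg adjusted p under 0.05 over the 13246 genes tested, and fold changes are on the log2 scale. Gene groups were taken from 30 lists written before the data were examined, of which 29 had enough measured members, and each was tested with camera.

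The libraries parted by strain and by treatment. The first principal component held 50.7% of the variance and set PWD apart from B6 and C57, and the second held 27.1% and separated LPS from untreated cells within each strain. Neither component held strain or treatment alone. The first also separated LPS from untreated cells within each strain, and the second also set C57 above B6 and PWD in each treatment. In PWD_Untreated and C57_LPS the libraries also parted by mouse number, which goes with sex. Structural RNA took 41.9% and 40.3% of TPM in PWD_Untreated 1 and 2 against 29.3% and 28.8% in 3 and 4 (second component 3.85 and 6.73 against 21.1 and 21.3). It took 39.9% and 41.2% in C57_LPS 1 and 2 against 31.6% and 33.4% in 3 and 4 (-9.12 and -13.6 against 1.41 and 0.913). Libraries of one group correlated with r of 0.980 to 0.990 across genes. The response to LPS, gene by gene, correlated across the 13246 genes with r = 0.836 between C57 and B6, 0.738 between PWD and B6 and 0.768 between PWD and C57 (genes are not independent replicates). LPS changed 6022 genes in the same direction in all 3 strains, 821 higher and 5201 lower (3981 with only the mice numbered 1 and 2), and 260 genes were called in opposite directions in at least 1 pair of strains. After median-of-ratios scaling, which sets the typical gene to no change, the shared genes were 2242 higher and 2036 lower, and 476 were called in opposite directions.

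**Figure D1:**
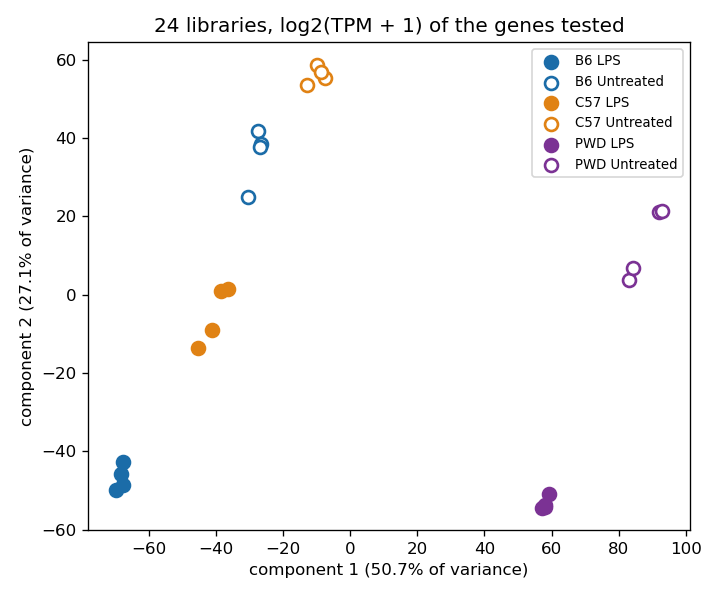
The 24 libraries on the first 2 principal components of log2(TPM + 1), with the percent of variance on each axis; each point is 1 library, filled for LPS and open for untreated, coloured by strain. The 8 PWD libraries lie to the right of the other 16, and in each strain the LPS libraries lie below the untreated ones.

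In B6 cells LPS raised every one of the 23 inflammatory cytokines measured (camera adjusted p = 3.6e-31, or 0.00115 with an estimated correlation). Il6 went from a mean of 3.75 TPM (SD 0.814, 4 libraries) to 943 TPM (SD 218), a log2 change of 7.62 (SE 0.17, limma adjusted p = 4.1e-21). Il12b, the subunit shared by IL-12 and IL-23, rose by 6.96, Il1b by 4.53, Tnf by 2.25 and the anti-inflammatory Il10 by 3.51 (6.08 with a pseudocount of 0.1 TPM). Nos2, the inducible nitric oxide synthase, rose by 6.78, and Ptgs2, the inducible cyclooxygenase that starts prostaglandin synthesis, by 6.38; of their list of nitric oxide, prostaglandin and itaconate enzymes 16 of 21 rose and 4 fell (adjusted p = 7.5e-16, or 0.0299 with an estimated correlation). The histamine-forming enzyme Hdc (4.40) and the acute-phase protein Saa3 (4.42) were also among the genes that rose.

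Group by group, 16 of 22 chemokines rose, 1 fell and 5 were not called (camera adjusted p = 5.2e-18, or 0.0107 with an estimated correlation), with Cxcl1, a neutrophil attractant, at 4.89, Ccl5 at 4.44 and Cxcl10 at 3.48. Of 39 type I interferon-stimulated genes 38 rose and 1 was not called, by a median of 2.13 (adjusted p = 1.5e-44, or 0.0299 with an estimated correlation), among them the antiviral Rsad2 (3.76) and the exonuclease Isg20 (3.65). Ifi205 (4.84) belongs to a family of near-identical genes, so its value is uncertain. The interferon gene Ifnb1 itself rose by 1.56 (limma adjusted p = 7.1e-07), or by 2.71 with a pseudocount of 0.1 TPM. Among guanylate-binding proteins and immunity-related GTPases, which attack vacuoles that hold microbes, 16 of 17 rose (adjusted p = 5.5e-20, or 0.0154 with an estimated correlation), with Iigp1 at 3.65 and Gbp5 at 3.24. The list of MHC class I presentation rose in 19 of 20 members (H2-T22 2.12, the peptide transporter Tap1 1.38, the transactivator Nlrc5 1.62, adjusted p = 1.0e-19, or 0.0325 with an estimated correlation). The list of dendritic cell maturation rose in 17 of 22 (Cd40 3.95, Ccl22 2.77, adjusted p = 5.2e-18, or 0.0364 with an estimated correlation). Brakes on Toll-like receptor signalling rose in 15 of 27 members and fell in 5 (adjusted p = 6.3e-09, but 0.258 with an estimated correlation), with Nfkbiz at 2.85, Tnfaip3 at 2.11 and Socs3 at 1.53. The endotoxin co-receptor Cd14 rose by 1.21 and the receptor Tlr4 stood at -0.84, or -0.29 with median-of-ratios scaling. Of the inflammasome and cell death list 14 of 25 rose and 7 fell (adjusted p = 2.3e-06, 0.393 with an estimated correlation), among the risen the intracellular LPS sensor Casp4 (1.86) and the necroptosis effector Mlkl (2.08).

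Of 30 cell cycle genes 29 fell in B6, by a median of -1.50 (camera adjusted p = 1.0e-08, but 0.379 with an estimated correlation), as in Cdc20 (-2.31) and the cyclin Ccnb1 (-2.06). Of 19 genes of cholesterol synthesis and uptake 18 fell (adjusted p = 1.4e-04, but 0.393 with an estimated correlation), as in Dhcr7 (-1.97), Stard4 (-1.63) and Sqle (-1.47), the last 2 at -1.03 and -0.98 after quantile normalization. The fatty acid desaturase Scd2 (-3.23), the chemokine receptor Ccr2 (-2.22) and Myc (-2.43) fell too. Over all genes 9480 changed, 1575 higher and 7905 lower, around a median of -0.43; with median-of-ratios scaling the split was 4129 higher and 4024 lower, and after quantile normalization 3354 and 4659, so the share of genes that fell depends on the scaling. For every list named for B6, the counts adjusted over the list alone were the same as those over all genes.

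C57 cells raised inflammatory cytokines, chemokines and interferon-stimulated genes with LPS. Il6 rose by 6.29 (SE 0.17, limma adjusted p = 2.6e-19), Il12b by 5.96, Ptgs2 by 5.70, Nos2 by 4.96, Tnf by 2.45 and Il10 by 2.24 (5.10 with a pseudocount of 0.1 TPM). Of the inflammatory cytokines 20 of 23 rose and 3 were not called (camera adjusted p = 9.6e-34, or 7.2e-04 with an estimated correlation), with Tnfsf15 at 4.71. Of the chemokines 15 of 22 rose (adjusted p = 1.5e-19, or 0.00585 with an estimated correlation), with Cxcl1 at 4.41 and Ccl5 at 4.35. Interferon-stimulated genes rose in 38 of 39 members (Rsad2 3.79, Ifit2 3.34, adjusted p = 5.4e-55, or 0.0155 with an estimated correlation). Guanylate-binding proteins and GTPases rose in 15 of 17 (Gbp5 3.44, adjusted p = 9.7e-25, or 0.00585 with an estimated correlation). Dendritic cell maturation rose in 15 of 22 members and fell in 1 (Cd40 3.32, adjusted p = 1.6e-15, but 0.0596 with an estimated correlation). All 19 genes of cholesterol synthesis fell (Stard4 -1.69, Sc5d -1.38, adjusted p = 9.1e-07, but 0.287 with an estimated correlation). So did 29 of 30 cell cycle genes (Mcm7 -1.15, Rrm2 -1.14, adjusted p = 6.1e-06, but 0.508 with an estimated correlation). Counts adjusted over the list alone were the same for these lists. In all 8279 genes changed, 1371 higher and 6908 lower around a median of -0.32, or 3291 higher and 3495 lower with median-of-ratios scaling and 2737 and 4152 after quantile normalization.

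PWD cells raised Il12b with LPS by 8.44 (SE 0.23, limma adjusted p = 1.4e-17), from 2.17 to 1107 TPM, and Ccl5 by 6.88, from 6.57 to 880 TPM. Il6 rose by 6.29, Cxcl1 by 5.06, Tnf by 2.81 and Il10 by 2.41, while Nos2 rose by 3.75 and Ptgs2 by 4.19. With a pseudocount of 0.1 TPM Il10 rose by 5.47 and Nos2 by 5.84. All 39 interferon-stimulated genes rose, by a median of 3.04 (camera adjusted p = 6.9e-64, or 0.011 with an estimated correlation), as in Ifit1 (5.01), the ubiquitin-like Isg15 (4.93), Oasl1 (4.63) and the antiviral GTPase Mx2 (4.32). Ifnb1 was higher by 0.64 (limma adjusted p = 0.0134), or by 2.47 with a pseudocount of 0.1 TPM (adjusted p = 9.6e-05), but without PWD_LPS replicate 3 it was higher by 0.52 and no longer called (adjusted p = 0.0561). Guanylate-binding proteins and GTPases rose in 16 of 17 members (Gbp5 4.88, adjusted p = 3.7e-24, or 0.00983 with an estimated correlation). The maturation list rose in 17 of 22, with 3 lower (Cd40 3.26, adjusted p = 5.3e-16, but 0.0613 with an estimated correlation). The chemokines split into 15 that rose and 5 that fell (adjusted p = 3.5e-14, or 0.0162 with an estimated correlation). Cholesterol synthesis fell in all 19 members, by a median of -1.61 (Sqle -2.11, Msmo1 -2.11, adjusted p = 1.2e-10, but 0.105 with an estimated correlation). The cell cycle fell in 27 of 30 members (28 adjusted over the list alone; Mcm2 -1.52, Mcm7 -1.44, adjusted p = 2.2e-04, but 0.587 with an estimated correlation). The cyclin Ccnd1, outside the list, fell too (-3.08). The small stromal and endothelial list was called higher (adjusted p = 0.0368, but 0.556 with an estimated correlation) although its median was -0.12 and its mean 0.12. In all 8410 genes changed, 1464 higher and 6946 lower around a median of -0.32, or 3591 higher and 3460 lower with median-of-ratios scaling and 2875 and 4273 after quantile normalization. With only the mice numbered 1 and 2 the count was 5600.

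**Figure D2:**
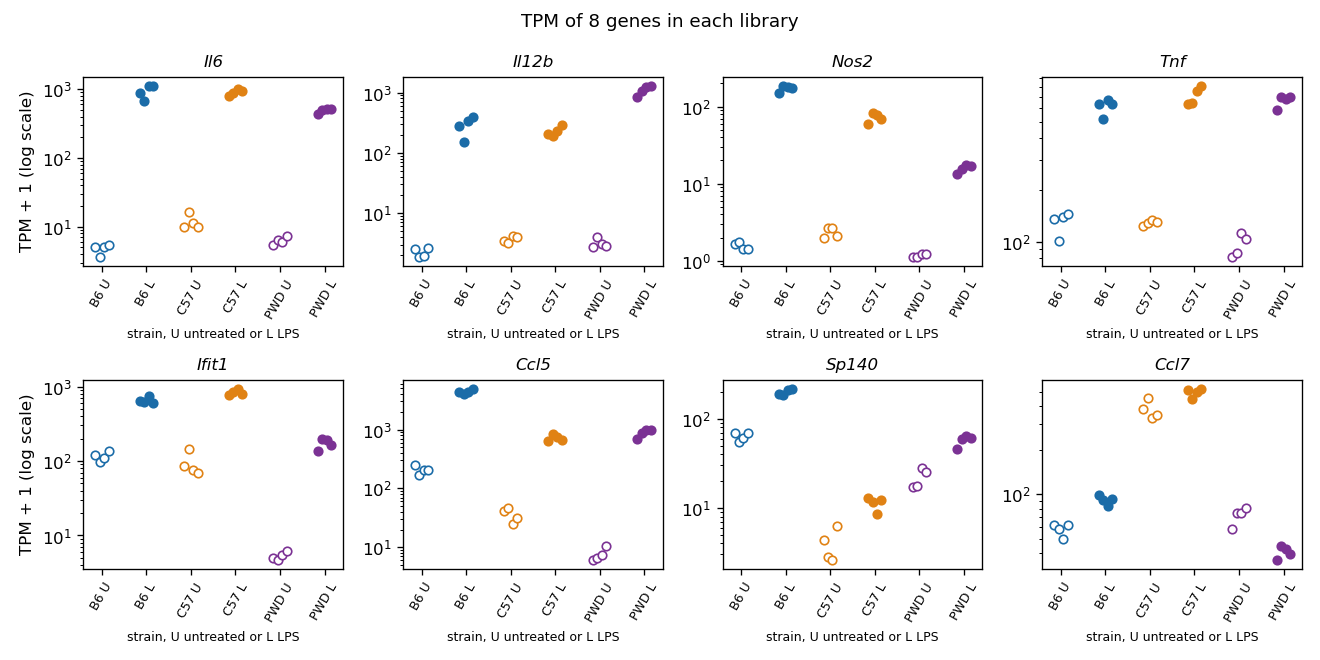
TPM + 1 on a log axis for 8 genes in each of the 24 libraries, by strain and treatment (U untreated, open; L LPS, filled); each point is 1 library and every panel has its own scale. Nos2 after LPS falls from B6 to C57 to PWD, Il12b after LPS is highest in PWD, and untreated PWD cells hold the least Ifit1 and Ccl5.

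Untreated PWD cells held far less of the interferon-stimulated transcripts than untreated B6 cells. Of 39 such genes 38 were lower and 1 higher, by a median of -2.67 (camera adjusted p = 1.4e-32, but 0.133 with an estimated correlation). Ifit1 stood at 4.33 TPM (SD 0.663, 4 libraries) against 115 TPM (SD 16.1), a log2 difference of -4.44 (limma adjusted p = 2.3e-17), with Ifit3 at -5.24, the deubiquitinase-like Usp18 at -4.43 and Oas1a at -4.41. Guanylate-binding proteins and GTPases were lower in 14 of 17 members (15 adjusted over the list alone; Gbp2 -3.75, Irgm1 -3.60, adjusted p = 3.8e-10, but 0.133 with an estimated correlation). The interferon-inducible chemokines Cxcl10 (-4.86) and Ccl5 (-4.78) were lower. Ifit, Oas, Gbp, H2 and Ifi genes belong to families of close copies, so that single members are uncertain where a strain's sequence departs from the reference.

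Antigen presentation and dendritic cell maturation were also lower in untreated PWD cells. All 15 MHC class II genes were lower (H2-Eb1 -5.08, H2-Ob -3.33, camera adjusted p = 6.0e-09, but 0.185 with an estimated correlation). So were 19 of 20 MHC class I genes (H2-T22 -3.86, Tap1 -2.38, adjusted p = 2.8e-15, but 0.133 with an estimated correlation). Of the maturation genes 19 of 22 were lower (20 adjusted over the list alone; the homing receptor Ccr7 -3.28, Ccl22 -2.80, Tnfrsf9 -6.43, adjusted p = 1.5e-10, but 0.185 with an estimated correlation). Markers of cell types, in lists that share some genes with these (such as Ciita), moved with them: 13 of 15 conventional dendritic cell markers were lower (Irf8 -1.76, Kmo -2.40, adjusted p = 5.2e-06, but 0.185 with an estimated correlation). Lower too were 15 of 20 macrophage and monocyte markers (the complement genes C1qb -5.41 and C1qa -4.66, adjusted p = 1.2e-05, but 0.292 with an estimated correlation), and all 6 B cell and plasmacytoid dendritic cell markers (Tcf4 -1.78, Bst2 -1.54, adjusted p = 1.7e-04, but 0.133 with an estimated correlation). The list of mast cell, basophil and eosinophil markers was not called, with 5 of 9 higher and 1 lower (adjusted p = 0.205), among the higher Prg2 (5.64) and Epx (4.52). The neutrophil granule gene Camp (4.55) was higher, while of all neutrophil and granulocyte precursor markers 10 were higher and 7 lower (camera adjusted p = 0.954).

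Cholesterol synthesis was higher in 16 of 19 members in untreated PWD cells (Dhcr7 2.92, Mvd 1.72, camera adjusted p = 7.4e-05, but 0.494 with an estimated correlation). The cell cycle was higher in 24 of 30 (Rrm2 1.41, Mcm2 1.25, adjusted p = 0.00112, but 0.71 with an estimated correlation). Among the largest differences, Lyz1 (6.82) and the scavenger receptor Marco (3.54) were higher, and the chitinase-like Chil3 was lower (-8.19), at 0.948 against 556 TPM, as was the pentraxin Ptx3 (-7.46). Nnt, the mitochondrial transhydrogenase that C57BL/6J mice lack in functional form, was higher by 2.04 (limma adjusted p = 2.3e-13). Il1b (1.30) and Cd14 (1.18) were higher and Tnf (-0.44, adjusted p = 0.00214) lower. The inflammasome genes Mefv (-2.49) and Casp1 (-1.27) were lower. In all 7544 genes differed, 4930 higher and 2614 lower around a median of 0.14, or 4181 higher and 3998 lower with median-of-ratios scaling and 4061 and 4332 after quantile normalization. Chil3, Lyz1, Ear1 (5.77), Rnase2a (5.63), Bcl2a1a (-7.63), Ifi27l2a (-7.65), Klk1b11 (-8.56) and Ifi202b (5.68) are members of duplicated families and their differences are uncertain. Pseudogenes took 3.78% of TPM in untreated PWD and 1.41% in untreated B6 cells (means of 4 libraries).

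After LPS, PWD cells held less Nos2, Il6 and Il10 and more Il12b than B6 cells. Nos2 stood at 14.7 TPM (SD 1.94, 4 libraries) against 171 TPM (SD 16.4), a log2 difference of -3.45 (limma adjusted p = 4.3e-19). Il6 (-0.92, adjusted p = 3.4e-05), Il10 (-1.21) and Ifnb1 (-1.43, or -2.34 with a pseudocount of 0.1 TPM) were lower, and Il12b was higher by 2.00, Il1b by 0.80 (0.46 with median-of-ratios scaling) and Cd14 by 1.39. Tnf did not pass the test, at 0.12 (adjusted p = 0.364), and its sign depends on the scaling: -0.22 (adjusted p = 0.0351) with median-of-ratios scaling and 0.30 (adjusted p = 0.00585) after quantile normalization. Tlr4 stood at -0.03 (adjusted p = 0.782), at 0.04 without B6_LPS replicate 3, and at -0.37 (adjusted p = 0.000204) with median-of-ratios scaling.

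The interferon-stimulated genes stayed lower in PWD after LPS, 36 of 39 members by a median of -1.72 (Ifit3 -5.56, Oas1a -3.93, camera adjusted p = 9.3e-23, but 0.199 with an estimated correlation), with 2 higher, among them Ifi44l (3.91, or 7.14 with a pseudocount of 0.1 TPM). Chemokines were lower in 12 and higher in 6 of 22 members (Cxcl10 -4.62, Ccl12 -3.35, Ccl20 2.90, adjusted p = 5.9e-04, but 0.348 with an estimated correlation). With a pseudocount of 0.1 TPM Ccl12 stood at -5.19 and Ccl20 at 5.44. Guanylate-binding proteins and GTPases were lower in 14 of 17 (Iigp1 -4.50, Gbp2 -3.13, adjusted p = 9.3e-10, but 0.149 with an estimated correlation), and Gbp2b, a close copy within the family, was higher by 4.39. All 20 MHC class I genes (H2-T22 -4.31, adjusted p = 1.8e-18, but 0.149 with an estimated correlation) were lower. So were 21 of 22 maturation genes (Ccr7 -2.80, Tnfrsf9 -5.55, adjusted p = 2.2e-14, but 0.149 with an estimated correlation). Lower too were 13 of 15 MHC class II genes (14 adjusted over the list alone; H2-Eb1 -4.37, adjusted p = 9.1e-08, but 0.238 with an estimated correlation) and 10 of 15 conventional dendritic cell markers (Irf8 -2.80, adjusted p = 7.2e-06, but 0.234 with an estimated correlation). Also lower were 13 of 20 macrophage and monocyte markers, with 4 higher (adjusted p = 1.2e-05, but 0.298 with an estimated correlation), all 6 B cell and plasmacytoid dendritic cell markers (adjusted p = 2.9e-04, but 0.149 with an estimated correlation) and 14 of 25 inflammasome and cell death genes, with 5 higher (adjusted p = 5.8e-05, but 0.545 with an estimated correlation). Endotoxin sensing was called lower, with 16 of 37 lower and 11 higher (adjusted p = 0.0104, but 0.872 with an estimated correlation). The double-stranded RNA sensor Tlr3 (-3.87) and Ly86 (-2.79) were lower. Of the cell cycle list 29 of 30 were higher (Rrm2 2.54, Bub1b 2.04, Cdc20 1.99, adjusted p = 9.3e-08, but 0.433 with an estimated correlation). In all 9091 genes differed, 6580 higher and 2511 lower around a median of 0.28, or 4724 higher and 4519 lower with median-of-ratios scaling and 4624 and 4534 after quantile normalization.

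Tests of the difference between the LPS responses of PWD and B6 called 3111 genes. The log2 response, positive for a rise and negative for a fall, was higher in PWD in 2117 and lower in 994, so that a higher value can be a larger rise or a smaller fall. The rise of Nos2 was smaller in PWD, with a difference of -3.03 (SE 0.17, limma adjusted p = 6.6e-13), as were those of Hdc (-4.08), the iron hormone gene Hamp (-3.52), Ptgs2 (-2.19) and Il12a (-2.39), while Ccl2 rose in B6 and fell in PWD (-1.77). With a pseudocount of 0.1 TPM the differences came nearer to 0, at -2.20 for Nos2 (adjusted p = 1.6e-06), whose untreated means of 0.164 TPM in PWD and 0.560 TPM in B6 lie below the offset of 1 TPM, and at -1.24 for Il12a (adjusted p = 0.0217). Il6 (-1.33, adjusted p = 1.9e-04, or -0.84 after quantile normalization) and Il10 (-1.09, adjusted p = 2.8e-04) rose less too, but with a pseudocount of 0.1 TPM Il10 stood at -0.61 and was not called (adjusted p = 0.295). Rises were larger in PWD for Il12b (1.49), Ccl5 (2.44), the chemokine Ccl20 (2.68, or 4.17 with a pseudocount of 0.1 TPM), the epithelial-type cytokine Tslp (2.71) and Tnf (0.56, adjusted p = 0.0137, or 0.84 after quantile normalization). Ccl5 nevertheless stayed lower in PWD than in B6 after LPS (-2.34), from a log2 difference of -4.78 in untreated cells. Interferon-stimulated genes rose more in PWD in 24 of 39 members and less in 2 (29 and 2 adjusted over the list alone), by a median of 0.83 (Ifit1 2.50, Rtp4 2.96, Mx2 2.98, camera adjusted p = 1.5e-09, but 0.956 with an estimated correlation). The fall of cell cycle genes was smaller in PWD in 21 of 30 (Cdc20 1.58, Ccnb1 1.54, adjusted p = 2.1e-08, but 0.956 with an estimated correlation). The response of cholesterol synthesis was lower in PWD in 9 of 19 and higher in 1 (10 and 1 adjusted over the list alone; Hmgcs1, which fell further, -0.91; Idi1, which rose in B6 and fell in PWD, -1.99; adjusted p = 4.4e-06, but 0.956 with an estimated correlation). MHC class I genes had lower responses in 8 of 20 members and higher ones in 1 (10 and 1 adjusted over the list alone; H2-Q7 -0.73, Tap1 0.64, or 1.06 after quantile normalization, adjusted p = 8.6e-05, but 0.956 with an estimated correlation). The keratin Krt6b (3.69) and the hyaluronan synthase Has1 (3.43) had among the largest rises gained. The split and the count depend on the scaling, around a deposited median of 0.14. They were 1980 higher and 2228 lower with median-of-ratios scaling, 2261 and 1886 after quantile normalization, and 4508 and 1239, or 5747 in all, with structural RNA left out.

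Untreated C57 cells held less Sp140, Apoe and Ccl5 and more Ccl7 and Ccl2 than untreated B6 cells. Sp140, a nuclear body protein, stood at 2.99 TPM (SD 1.69, 4 libraries) in C57 against 62.7 TPM (SD 7.13) in B6, a log2 difference of -4.08 (limma adjusted p = 4.6e-12). Apoe, the apolipoprotein made by macrophages and liver (-3.32), the retinoic acid enzyme Aldh1a2 (-2.72), Slfn1 (-2.80) and Ccl5 (-2.54) were lower. The monocyte chemokines Ccl7 (2.70) and Ccl2 (1.85), neighbours on the same chromosome (Ccl7 at chromosome 11, 82045712 to 82047525; Ccl2 at chromosome 11, 82035571 to 82037453), were higher, with Marco (2.53), the lactoferrin gene Ltf (2.78) and Serpinb1a (2.61). Sp140 and the genes Tgtp1 (2.29), Psme2b (-2.60), Rnu1b2 (3.45, or 5.90 with a pseudocount of 0.1 TPM) and Rnase2a (2.65) have near-identical relatives and are uncertain.

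Dendritic cell maturation was lower in untreated C57 cells in 16 of 22 members (17 adjusted over the list alone; Ccl22 -1.76, Tnfrsf9 -2.02, the actin bundler Fscn1 -1.69, Ccr7 -1.62, camera adjusted p = 2.7e-18, but 0.206 with an estimated correlation). MHC class II was lower in 11 of 15 (H2-Ab1 -1.60, H2-Aa -1.60, Cd74 -1.54, the transactivator Ciita -1.04, adjusted p = 1.6e-11, but 0.206 with an estimated correlation). MHC class I was lower in 15 of 20 (16 adjusted over the list alone; H2-T23 -0.68, adjusted p = 3.8e-11, but 0.212 with an estimated correlation), and interferon-stimulated genes were lower in 24 of 39 (26 adjusted over the list alone; Ifit3 -0.69, adjusted p = 5.7e-15, but 0.301 with an estimated correlation). Conventional dendritic cell markers were lower in 10 and higher in 2 of 15 (adjusted p = 3.8e-07, but 0.208 with an estimated correlation), while 15 of 21 neutrophil and granulocyte precursor markers were higher (adjusted p = 0.114). All 30 cell cycle genes were higher (Rrm2 1.29, Mcm2 1.25, adjusted p = 9.6e-13, but 0.293 with an estimated correlation). So were 12 of 17 glycolysis genes (Pfkl 1.03, the lactate exporter Slc16a3 0.94, adjusted p = 0.00581, but 0.856 with an estimated correlation). Il6 (1.30) and Il1b (0.72) were higher and Nnt was higher by 0.55 (limma adjusted p = 0.0015), or by 0.36 with median-of-ratios scaling and 0.31 after quantile normalization. In all 5135 genes differed, 4219 higher and 916 lower around a median of 0.17, or 2673 higher and 2592 lower with median-of-ratios scaling and 2836 and 2506 after quantile normalization. With only the 2 mice per strain numbered 1 and 2 the count was 3393.

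After LPS the maturation genes were lower in C57 than in B6 in all 22 members, by a median of -1.30 (camera adjusted p = 3.4e-24, but 0.0763 with an estimated correlation): Ccl22 stood at -2.37, Fscn1 at -2.31 and Cd83 at -2.19 (limma adjusted p = 1.5e-11). MHC class I was lower in 18 of 20 (H2-T23 -1.06, adjusted p = 2.3e-17, but 0.142 with an estimated correlation). MHC class II was lower in 11 of 15 (Cd74 -1.65, H2-Eb1 -1.57, adjusted p = 2.4e-08, but 0.286 with an estimated correlation), and interferon-stimulated genes were lower in 22 of 39 (Isg20 -1.41, adjusted p = 8.7e-14, but 0.336 with an estimated correlation). The cell cycle was higher in 29 of 30 (Ccnb1 2.25, Plk1 2.01, adjusted p = 4.6e-15, but 0.286 with an estimated correlation). Sp140 (-4.16), Apoe (-3.09), the small GTPase gene Arl5c (-3.16) and the serotonin transporter Slc6a4 (-2.64) were lower, and Ccl1 (2.96), Ccl7 (2.43) and tissue factor, F3 (2.60), were higher. Markers of cell types moved as well: 9 of 15 conventional dendritic cell markers were lower and 3 higher (Irf8 -1.32, camera adjusted p = 2.2e-05, but 0.286 with an estimated correlation). Of 20 macrophage and monocyte markers 11 were higher and 5 lower (adjusted p = 0.491), and of 21 neutrophil and granulocyte precursor markers 12 were higher and 3 lower (adjusted p = 0.919); adjusted over the list alone these were 12 and 5, and 14 and 4. Il10 (-1.36) and Nos2 (-1.25) were lower and Tlr4 higher (0.79, or 0.39 with median-of-ratios scaling). Il6 (-0.03, adjusted p = 0.911), Il12b (-0.26, adjusted p = 0.342) and Tnf (0.21, adjusted p = 0.117) did not pass the test. With median-of-ratios scaling Il6 stood at -0.44 (adjusted p = 0.0253), Il12b at -0.67 (adjusted p = 0.0116) and Tnf at -0.20. After quantile normalization Tnf stood at 0.37 (adjusted p = 0.00178) and Il6 at 0.085, and the sign of Il6 also turned with single libraries left out (up to 0.066). With a term for sex, chosen after seeing the data, Tnf was called (adjusted p = 0.0412), and without B6_LPS replicate 2 Il12b stood at -0.55 (adjusted p = 0.0103). In all 7783 genes differed, 6500 higher and 1283 lower around a median of 0.29, or 3642 higher and 3933 lower with median-of-ratios scaling and 3888 and 3288 after quantile normalization.

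The LPS response differed between C57 and B6 in 1896 genes, with a higher log2 response in C57 in 1447 and a lower one in 449. Nos2 rose less in C57, with a difference of -1.82 (SE 0.17, limma adjusted p = 2.1e-07), and so did Hdc (-1.82), Saa3 (-1.46), Il6 (-1.33) and Il10 (-1.27), the last not called with a pseudocount of 0.1 TPM (-0.98, adjusted p = 0.1001). Il6 started higher in untreated C57 cells (1.30) and was not called after LPS (-0.03, limma adjusted p = 0.911). With median-of-ratios scaling it stood at -0.44 after LPS (limma adjusted p = 0.0253). Inflammatory cytokines had lower responses in 8 of 23 members and higher ones in 2 (14 and 3 adjusted over the list alone, camera adjusted p = 2.8e-07, but 0.545 with an estimated correlation), with Csf2, the gene of GM-CSF, among those that rose more (1.72). Enzymes of nitric oxide, prostaglandin and itaconate synthesis had lower responses in 10 of 21 and higher ones in 3 (11 and 4 adjusted over the list alone, adjusted p = 2.7e-05, but 0.545 with an estimated correlation). Maturation genes had lower responses in 5 of 22 (11 adjusted over the list alone; Cd83 -0.88, or -0.53 after quantile normalization, Cd200 -1.10, adjusted p = 1.5e-07, but 0.545 with an estimated correlation). The fall of the cell cycle was smaller in C57 in 20 of 30 members, and 1 had a lower response (23 and 1 adjusted over the list alone; Ccnb1 1.38, Cdc20 1.36, adjusted p = 6.0e-13, but 0.545 with an estimated correlation), and that of Myc by 1.68. The inhibitor of ERK signalling Dusp6 fell less in C57 (1.78), Casp4 (-0.70) and Mlkl (-0.85) rose less, and Tnfrsf13b rose in B6 and fell in C57 (-1.76). In all 7 lists were called, 11 when each mouse's paired libraries were blocked by replicate number, 12 without B6_LPS replicate 1, 3 after quantile normalization, and 0 with an estimated correlation. The gene count depends on the scaling, with 1400 higher and 1980 lower responses under median-of-ratios scaling, 1448 and 1243 after quantile normalization and 3642 and 734 with structural RNA left out, around a deposited median of 0.12. With only the mice numbered 1 and 2 it was 725.

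The direct comparison of PWD with C57 called 6126 genes in untreated cells, 2656 higher in PWD and 3470 lower around a median of -0.04, and 7179 after LPS, 3236 higher and 3943 lower around a median of -0.05. With median-of-ratios scaling these were 3638 and 3648, and 4339 and 4067. The LPS response differed between PWD and C57 in 1510 genes, with a log2 response higher in PWD in 717 and lower in 793, or 1486 and 1375 with median-of-ratios scaling, 1535 and 1431 after quantile normalization, 1435 and 1345 with structural RNA left out, and 2378 in all with only the mice numbered 1 and 2.

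**Figure D3:**
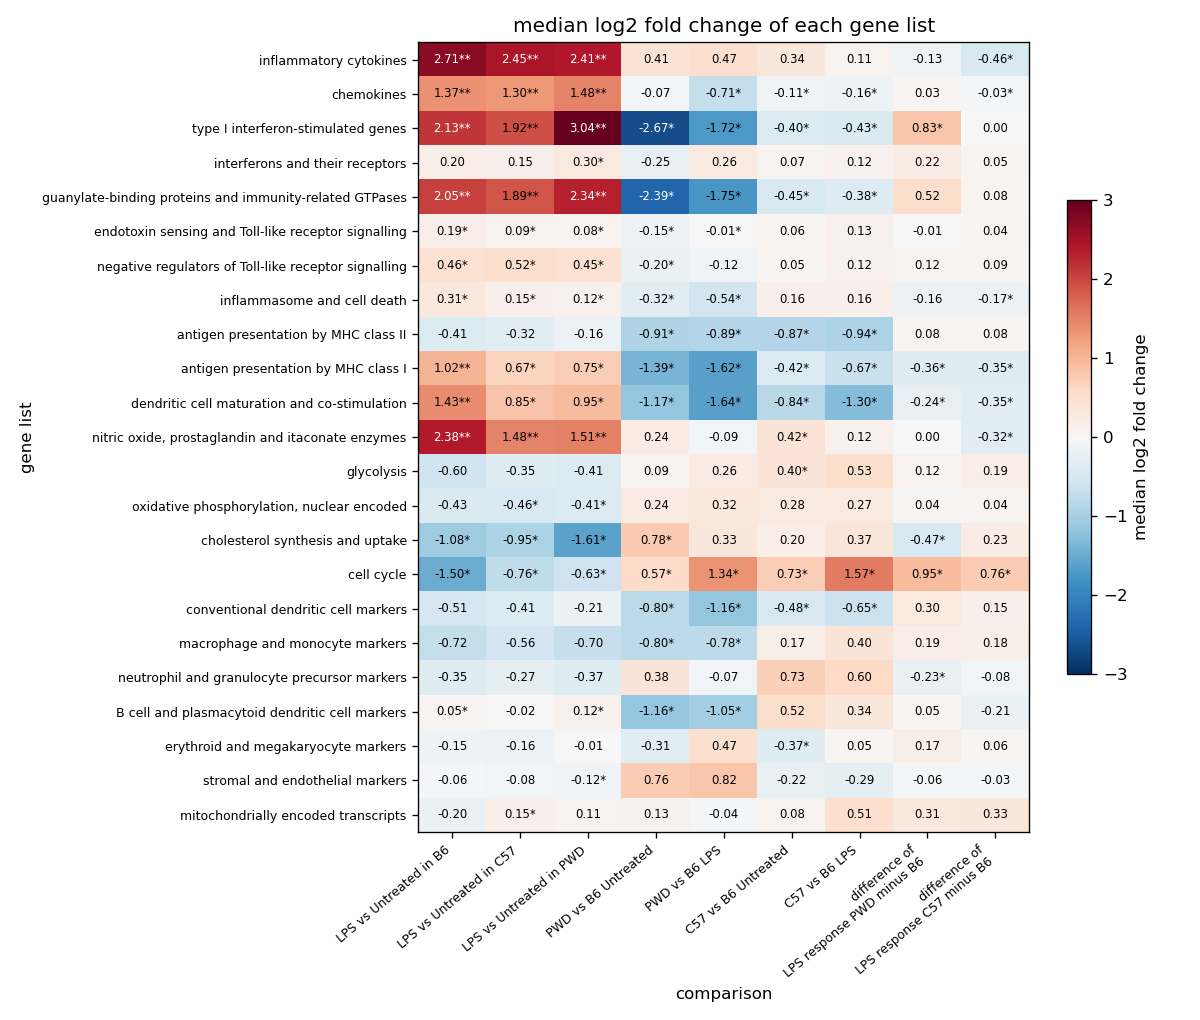
Median log2 fold change of the members of each gene list called in at least 1 comparison (colour and number), by list and comparison; 1 star marks a camera adjusted p under 0.05 and 2 stars one that stays under 0.05 with an estimated correlation. Calls with 2 stars are found only in the 3 comparisons of LPS with untreated cells.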

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

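The tests of explanations in this part were chosen after the main results were seen. Those chosen after the values they measure were also known are the bound on pseudogenes lying on chromosome 11, the share of chromosome 11 genes higher in C57 and those on interferon-stimulated genes.

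One library stood apart from its group among 91 sets of 4 libraries tested for an outlying value, of which chance alone flags about 1 in 20: Tnf in PWD_LPS replicate 1, at 584.7 TPM against 680 to 695 TPM in the other 3. The LPS response differed between strains by limma's test of the difference in 3111 genes for PWD and B6, 1896 for C57 and B6 and 1510 for PWD and C57, and in 6 and 7 gene lists for the first 2 of these, but in 0 and 0 lists with an estimated correlation, and 8 and 15 of 35 splits of the mice called as many, 5 and 14 of them splits that exchange 1 mouse and keep a part of the difference.

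Named genes whose log2 response (positive for a rise, negative for a fall) was lower in PWD than in B6 were Hdc (-4.08), Hamp (-3.52), Apol9b (-3.39), Apol7c (-3.26), Iigp1 (-3.12), Nos2 (-3.03), Il12a (-2.39), Ptgs2 (-2.19), Idi1 (-1.99), Ccl2 (-1.77), Cd70 (-1.45), Il6 (-1.33), Il10 (-1.09), Cd200 (-1.003), Ifnb1 (-0.92), Hmgcs1 (-0.91), Nlrc5 (-0.83) and H2-Q7 (-0.73). Those with a higher log2 response in PWD were Krt6b (3.69), Has1 (3.43), Ifi44l (3.34), Mx2 (2.98), Rtp4 (2.96), Tslp (2.71), Ccl20 (2.68), Ifit1 (2.50), Ccl5 (2.44), Cdc20 (1.58), Ccnb1 (1.54), Il12b (1.49), Tap1 (0.64) and Tnf (0.56), among which Cdc20 and Ccnb1 fell in both strains and fell less in PWD. Of those with a lower response Hmgcs1 fell further in PWD, and Idi1 and Ccl2 rose in B6 and fell in PWD.

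Log2 responses lower in C57 than in B6 were those of Olfr56 (-2.79), Nos2 (-1.82), Hdc (-1.82), Tnfrsf13b (-1.76; a rise in B6 and a fall in C57), Saa3 (-1.46), Il6 (-1.33), Il10 (-1.27), Il12a (-1.17), Cxcl9 (-1.17; not called when the paired libraries were blocked by mouse), Cd70 (-1.12), Cd200 (-1.10), Il12b (-0.999), Cd83 (-0.88), Cxcl11 (-0.86), Mlkl (-0.85), Casp4 (-0.70), H2-T22 (-0.47) and Psme1 (-0.46). Csf2 rose more in C57 (1.72), and Dusp6 (1.78), Myc (1.68), Ccnb1 (1.38), Cdc20 (1.36) and Plk1 (1.32) fell less. The calls of Nlrc5 and Ifnb1 for PWD and of Psme1, H2-T22 and Il12b for C57 were lost under several of the alternatives. The value itself moved by over 1.5 times in 3 of these losses: Ifnb1 with a pseudocount of 0.1 TPM (-0.24, adjusted p = 0.838), and Nlrc5 (-0.55, adjusted p = 0.1095) and H2-T22 (-0.24, adjusted p = 0.242) after quantile normalization. In the others the calls ended at -0.63 to -0.87 for Nlrc5, -0.79 to -0.94 for Ifnb1, -0.36 to -0.49 for Psme1, -0.37 to -0.47 for H2-T22 and -0.72 to -1.04 for Il12b. With a pseudocount of 0.1 TPM the calls of Cxcl11 (-0.31, adjusted p = 0.652), Cxcl9 (-0.62, adjusted p = 0.468), Cd70 (-1.22, adjusted p = 0.159), Il12a (-0.84, adjusted p = 0.148) and Il10 (-0.98, adjusted p = 0.1001) for C57 and of Il10 (-0.61, adjusted p = 0.295) and Cd70 (-1.17, adjusted p = 0.153) for PWD were lost too.

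The differences between C57 and B6 gathered on chromosome 11, where 48 of 944 protein-coding genes (5.08%) differed at least 2-fold in both treatments, against 2.39% elsewhere. Reads shared between near-identical genes do not account for it, since over genes with no such copy the share stayed higher (5.04% against 2.50%, Fisher's exact p = 7.9e-05). A loss of reads from non-reference alleles does not account for the 61.9% of the 42 such genes that were higher in C57 (lower 95% bound 45.6%), but could for the 16 that were lower. That share is for TPM as deposited and was not repeated with another scaling. Over all genes the 2-fold split between C57 and B6 was 345 higher and 159 lower untreated and 953 and 244 after LPS. With median-of-ratios scaling it was 182 and 223, and 400 and 592. If C57 libraries carried PWD-like alleles on this chromosome, C57 minus B6 would follow PWD minus B6 there with the steepest slope, and with different mice on each side the slope was 0.408 on chromosome 11 against at most 0.338 on another chromosome, though the correlation was higher on chromosome 15 (r of 0.648 against 0.628). PWD and C57 also differed less often there than over the other chromosomes pooled, at 5.83% of genes against 7.96% (Fisher's exact p = 0.0186), but chromosomes 8 (5.20%) and X (3.93%) lay lower still. This is a hypothesis that fits these 2 tests, but genotypes were not analysed here. The share of genes with the sign of PWD, however, does not set the chromosome apart (91.2% there, 89.4% elsewhere). The same B6 libraries stand on both sides of that share, which can raise it on every chromosome and leaves little room for a difference. Ccl7 and Ccl2, higher by 2.70 and 1.85 in untreated C57, were higher by only 0.31 and 0.35 in untreated PWD. After LPS both were lower in PWD (-1.19 and -1.42).

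Of 807 pseudogenes tested, 312 were at least 2-fold higher in PWD than in B6 in both treatments and 26 lower. One explanation is that reads of a parent gene whose PWD sequence differs from the reference go to its pseudogenes. Then C57, if its chromosome 11 is PWD-like, would raise those whose parent lies on chromosome 11, wherever the pseudogene itself lies: 10 of 18 rose in C57, against 6 of 281 with a parent elsewhere (Fisher's exact p = 2.2e-10). A rise in C57 here is a call of at least 2-fold in either treatment. Pseudogenes were taken as independent, although those of the same parent would share its stray reads, so this p and the bounds below are only a guide. On the same condition expression of the pseudogene's own locus predicts the reverse, but 0 of 14 lying on chromosome 11 with a parent elsewhere rose (Fisher's exact p = 1 against the others; upper 95% bound 23.2%, below the lower bound of 30.8% for a parent on chromosome 11). Since the condition stays a hypothesis, and 281 of the 299 have a parent elsewhere, expression of the pseudogenes' own loci in PWD cannot be told apart from a strain variant against the reference.

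Interferon-stimulated genes were low in untreated PWD cells, by a median of -2.67. Scaling of TPM does not account for it, since the median was -2.78 with median-of-ratios scaling. Loss of reads from PWD alleles gives the same ratio in both treatments only where a gene's reads come from that gene alone. There it cannot account for the part that LPS narrowed, in the 24 of 39 members whose own test called a larger rise in PWD (2 a smaller one). In families of close copies, such as Ifit and Oas genes, that condition was not tested, so the loss is not excluded there. Over all members, called or not, 33 differences were above 0 (exact binomial p = 1.4e-05 against an even split, 0.011 against the 65.5% of all genes). With median-of-ratios scaling 31 were above 0 (exact binomial p = 3.3e-04 against 51.1% of all genes). Genes were taken as independent in these tests. Against other genes the list was not called with an estimated correlation (camera adjusted p = 0.956). For the part that stayed after LPS (median -1.72) a strain variant against the reference cannot be told apart from lower expression, since no PWD sequence was used here. A lower basal interferon signal in PWD cultures stays open and untested, as do differences in cell makeup, with 13 of 15 conventional dendritic cell markers, 15 of 20 macrophage and monocyte markers and all 6 B cell and plasmacytoid dendritic cell markers lower, and the eosinophil genes Prg2 (5.64) and Epx (4.52) higher. The conventional dendritic cell list shares genes with that of MHC class II, so its count does not speak of cell makeup alone.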

How the results depend on the processing

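The text reports 13 gene counts, 9 list counts and 296 values of named genes, the latter those from which the text was drawn. Of 168 alternative values of the gene counts 144 stayed within 1.5 times, as did all 144 with 1 library left out; of 2952 alternative values of named genes 2913 kept direction and call, 22 lost and 10 gained a call and 7 turned sign, and of 2840 with 1 library left out 2787 kept both. Blocking by mouse, or between strains a term for the replicate number, changed no other count than the one below by more than 1.5 times. A term for sex, only the mice numbered 1 and 2 or 3 and 4, and TPM without structural RNA were chosen after seeing the data. The read depth is unknown, so the limit it sets cannot be given.

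Requiring a 2-fold change left, by construction, 2478, 1075 and 1376 genes for LPS in B6, C57 and PWD, 593 of them in all 3 strains the same way, 2223 and 2893 for PWD and B6 (untreated, LPS), 504 and 1197 for C57 and B6, 1797 and 1930 for PWD and C57, and 617, 229 and 346 for the differences of response PWD minus B6, C57 minus B6 and PWD minus C57. With only mice 1 and 2, the males, LPS in PWD gave 5600, the shared count 3981, C57 and B6 untreated 3393, and the differences C57 minus B6 725 and PWD minus C57 2378, while with only mice 3 and 4, the females and as few samples, all 13 gene counts stayed within 1.5 times. Without structural RNA the 3 differences of response gave 5747, 4376 and 2780; with median-of-ratios scaling C57 minus B6 gave 3380 and PWD minus C57 2861, and with quantile normalization the latter gave 2966. The cause was not tested.

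With an estimated correlation 7, 5 and 5 lists were called for LPS in B6, C57 and PWD and 0 in each of the 6 other comparisons. C57 and B6 after LPS gave 14 lists with no filter. The difference C57 minus B6 gave 11 lists with a filter of 5 TPM, 11 with the replicate block and 3 with quantile normalization, and 7 to 12 with 1 library left out, the most without B6_LPS replicate 1. The cause was not tested.

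With a pseudocount of 0.1 TPM these called values moved by over 1.5 times and stayed called: Il10 with LPS in B6 (6.08), C57 (5.10) and PWD (5.47), Ifnb1 in B6 (2.71) and PWD (2.47), Nos2 in PWD (5.84), Ifnb1 (-2.34), Ccl12 (-5.19), Ccl20 (5.44) and Ifi44l (7.14) for PWD and B6 after LPS, Rnu1b2 for C57 and B6 untreated (5.90) and after LPS (6.63), Olfr56 after LPS (-6.18), and the differences PWD minus B6 of Iigp1 (-1.91), Il12a (-1.24) and Ccl20 (4.17). Those moved as far by scaling were, with median-of-ratios scaling, Tlr4 (-0.29) and Sqle (-0.96) with LPS in B6, Il1b for PWD and B6 after LPS (0.46), Nnt for C57 and B6 untreated (0.36) and Tlr4 after LPS (0.39). With quantile normalization they were Stard4 (-1.03) and Sqle (-0.98) with LPS in B6, Nnt for C57 and B6 untreated (0.31), the differences PWD minus B6 of Il6 (-0.84), Tnf (0.84), Tap1 (1.06) and Ifnb1 (-1.47, but -0.24 and not called with a pseudocount of 0.1 TPM) and C57 minus B6 of Cd83 (-0.53) and Psme1 (-0.29).

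Values that turned sign were those of genes not called: Tnf with median-of-ratios scaling in PWD and B6 after LPS (-0.22) and in C57 and B6 untreated (-0.20) and after LPS (-0.20), Tnf in C57 and B6 untreated with quantile normalization (-0.13), without structural RNA (-0.065) and with 1 library left out (-0.11 to 0.064), Il6 in C57 and B6 after LPS with quantile normalization (0.085) and with 1 library left out (-0.19 to 0.066), Tlr4 in PWD and B6 after LPS with 1 library left out (-0.088 to 0.039), and the difference of the Tlr4 response PWD minus B6 with median-of-ratios scaling (-0.089) and with 1 library left out (-0.014 to 0.18). The cause was not tested.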

Other observations

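The tests of other splits below were written before their values were seen, except the counts over splits with 2 of each group on each side, and the genes on chromosome 11 were chosen after theirs were seen. Of 28 nuclear genes of oxidative phosphorylation, 26 in B6, 25 in C57 and 25 in PWD fell with LPS and none rose, by medians of -0.43, -0.46 and -0.41, while the median of all genes moved by -0.43, -0.32 and -0.32. The list was called lower in C57 and PWD but not in B6 (camera adjusted p of 0.017, 0.0368 and 0.0973), and in no strain with an estimated correlation (0.703, 0.748 and 0.853). With median-of-ratios scaling 9 rose and 2 fell in B6, 1 and 7 in C57, and 5 and 8 in PWD. Glycolysis split into 4 genes that rose and 11 that fell in B6, 2 and 10 in C57, and 2 and 10 in PWD, with camera adjusted p of 0.876, 0.897 and 0.71. Macrophage and monocyte markers fell with LPS in 12, 12 and 15 of 20 members in the 3 strains, with camera adjusted p of 0.879, 0.763 and 0.196.

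Of the genes on chromosome 11 that differed from B6 in the same direction in C57 and PWD, in both treatments, 6 picked with their values known are given here, and no gene group was tested among them. Lgals9, a galectin, stood at -1.77 untreated and -1.58 after LPS in C57 and at -3.25 and -2.62 in PWD, and Map3k14, the kinase of the non-canonical NF-kB pathway, at -1.27 and -1.33 in C57 and at -1.60 and -1.82 in PWD. The homing receptor Ccr7 stood at -1.62 and -1.46 in C57 and at -3.28 and -2.80 in PWD. Higher in both strains were the glutathione peroxidase Gpx3 (1.72 and 1.84 in C57, 3.14 and 3.22 in PWD), the purinergic receptor P2rx1 (2.76 and 1.91, 3.87 and 3.34) and the integrin Itgb3 (1.57 and 1.20, 2.84 and 5.40). Of the 57 genes on chromosome 11 that differed 2-fold between C57 and B6 in both treatments, 52 (91.2%) had the same sign in PWD in both, 35 of them 2-fold (61.4%). This does not set the chromosome apart, since on the other chromosomes 244 of 273 did (89.4%), 173 of them 2-fold (63.4%), and the same B6 libraries stand on both sides. Ccl2, Ccl7, Ccl1 and Tgtp1 were higher in C57 in both treatments but of opposite sign in PWD in 1 of them, as in Ccl2 (1.85 and 1.68 in C57, 0.35 and -1.42 in PWD), and the pseudogene Gm11425 was of opposite sign in both.

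Other splits of the same 8 libraries, or of the 8 mice for differences of response, were set beside the real one. A split that mixes the groups moves a real difference into the spread within groups and so lowers its own count. The gap to the real count is therefore no measure of chance, and only the rank of the real split among the 35 bears on it. For each of the 12 gene counts only 1 of 35 splits, the real one, gave as many genes. The real counts and the highest of the others were 9480 and 4916 for LPS in B6, 8279 and 2 in C57, 8410 and 2979 in PWD, 7544 and 3167 for PWD and B6 untreated, 9091 and 1 after LPS, 5135 and 29 for C57 and B6 untreated, 7783 and 2372 after LPS, and 6126 and 3 and 7179 and 1 for PWD and C57. For the differences of response they were 3111 and 0, 1896 and 1, and 1510 and 0. The splits with 4916, 2979, 3167 and 2372 genes exchanged 1 library between the groups and kept 3 in place. Splits with 2 of each group on each side, 18 per comparison, keep none of the difference between the groups. Their highest count was 1465 for PWD and B6 untreated and at most 5 in each other comparison. In untreated PWD and B6 libraries, differences other than strain thus called many genes. Among the 8 splits that part all 4 pairs of a strain, the highest after the real one were 3285 in B6, 1 in C57 and 4 in PWD. Only these 8 respect the pairing by mouse, and they are too few for a share under 0.05. For the 6022 genes shared by the 3 strains, 100 groupings were counted, the real one and random draws within each strain. Only the real one reached that count, and the highest of the random draws was 0.

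For the counts of gene lists the 35 splits do not decide whether chance can be excluded. As many lists as in the real split were called in 12 of 35 splits for LPS in B6 (13 real, 18 at most in another), 16 in C57 (14 and 18), 7 in PWD (16 and 18), 13 for PWD and B6 untreated (13 and 16), 16 after LPS (12 and 16), 9 for C57 and B6 untreated (11 and 15), 18 after LPS (8 and 16), and 8 and 15 for the differences PWD minus B6 (6 and 9) and C57 minus B6 (7 and 8). Of these splits 11, 13, 6, 12, 15, 8, 16, 5 and 14, in the same order, exchanged 1 library or mouse, which keeps a part of the difference between the groups. Among the 18 splits with 2 of each group on each side, which keep none of it, 2 called as many lists for LPS in C57, 1 for C57 and B6 after LPS, 2 for the difference PWD minus B6 and 0 for each of the other 6 counts, but 18 splits and the real one are too few for a share under 0.05. With an estimated correlation 7, 5 and 5 lists stayed called for LPS in B6, C57 and PWD. The splits that part all 4 pairs reached 15 lists in B6, 16 in C57 and 18 in PWD. Genes of a list may vary together between libraries more than the preset correlation of 0.01 allows, since calls were lost with an estimated correlation. The estimated correlations are not given here and the splits were not run with them, so this was not tested as the cause.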
